A study of Rattus norvegicus with 21 samples.

How the data were processed

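Liver RNA of 21 male rats was measured on 1-colour Affymetrix expression arrays, 1 array per animal, in a PBO study of 12 Sprague-Dawley rats and a DAM study of 9 F344 rats. Per the labels, livers of the PBO study were kept in RNAlater and those of the DAM study were frozen in liquid nitrogen. Total RNA was extracted with RNeasy kits, and biotin-labelled RNA was made by in vitro transcription. The authors deposited 1 table of probe set intensity values on a linear scale, made with MAS5 per the submitters' processing notes; the version is not given in the sources used here. The values bear a common scale, since the mean after trimming 2% at each end lay between 500.2 and 500.3 on every array. Groups, doses and replicate numbers were taken from the labels, which describe the replicates as biological, and every sample belonged to 1 group of 3.

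Of 31099 probe sets, 57 are array controls, 20826 had 1 gene symbol, 436 had several and 9780 had none in the platform annotation; symbols of 20758 probe sets were updated or kept through the Entrez identifier. A gene was represented by its probe set with the highest mean log2 value among those tested. Control probe sets were left out of tests. Values were transformed as log2(signal + 16) without further normalization, and probe sets whose mean over the arrays of a fit exceeded its 40th percentile were kept, which left 18625 per fit. Each study was fitted alone with all its arrays with limma (lmFit and eBayes with an intensity trend), and the difference of effects was fitted over both studies. P-values were adjusted with the Benjamini-Hochberg method over all probe sets tested, with a threshold of 0.05. The trend over PBO doses used dose as a number, in steps of 500 mg/kg.

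A total of 36 gene lists with 549 genes was tested with limma's camera with a preset correlation of 0.01, for lists with at least 4 measured genes, and again with an estimated correlation. The lists, designs, alternatives and the rule for named genes were fixed before the data were examined. The rule named the 8 largest rises and 8 largest falls past the threshold with separated groups in the comparison of the highest dose of each compound with its control. It named 5 and 5 in the other comparisons, up to 4 members of each described list with the smallest adjusted p, and 17 fixed genes, of which 13 had a named probe set. The other 4 fixed genes were not analysed here. Genes named outside the rule are stated as such.

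The fits were tested on simulated data with 50 probe sets changed at each size, drawn from the mean and residual spread of each of 18625 probe sets. For the simulated PBO 1500 mg/kg comparison, 12%, 42%, 78% and 98% of changes of 0.5, 1, 2 and 3 log2 units were recovered. For the simulated DAM 2000 mg/kg comparison the shares were 22%, 64%, 96% and 92%. There were 5 and 4 false calls, and no call with unchanged data. In these simulations a probe set had the same spread in every group, and probe sets were drawn independently. False calls from unequal spread between groups or from correlated probe sets could therefore not show. PBO 1500 arrays had root mean square deviations from their group mean of 0.355, 0.368 and 0.495, and other PBO arrays 0.276 to 0.313. Expected values for comparisons with shared controls came from 20 simulations of unchanged groups.

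Alternatives were other pseudocounts (1 and 64), no filter or the 60th percentile, quantile normalization and median scaling. Further alternatives were eBayes without the trend, the replicate number as a block, and only the arrays of both groups. Each array of the compared groups was also left out in turn. Array weights, and the fits at PBO 500 and 1000 mg/kg without PBO 1500 replicate 3, were added after the data were seen. Ratios of 3' to 5' signal were compared with two-sided exact permutation tests. Correlations across animals were tested with 100000 permutations within dose groups. R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9 were used. Arrays give no count-based depth, and the 3 arrays per group limit the precision.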

Results

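Gene expression was measured in the livers of male rats dosed with piperonyl butoxide (PBO, an insecticide synergist) or with dammar resin (DAM, a plant resin given in the diet), with 1 short oligonucleotide array per animal. The PBO study held 12 Sprague-Dawley rats, 3 at each of 0, 500, 1000 and 1500 mg/kg, dosed by mouth for 7 days. The DAM study held 9 F344 rats, 3 on a basal diet and 3 at each of 800 and 2000 mg/kg (2% and 5% of the diet), fed for 28 days. Every array reported 31099 probe sets, and the trimmed mean signal lay between 500.2 and 500.3 on all 21 arrays. Median signals ranged from 94.3 to 114 in the PBO study and from 76.0 to 86.2 in the DAM study. The number of arrays, 3 per group, limits the precision of every value. All changes are given on the log2(signal + 16) scale, which understates the change of genes with low signal. Beside them stands the standard error of the fit, with 3 animals per group. That error rests on a residual spread pooled over all arrays of the fit, and is not the spread of the compared animals alone.

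The highest dose of PBO answered what the compound changed in the liver after 7 days. Cyp1a1, a cytochrome P450 induced through the aryl hydrocarbon receptor, rose by 8.22 ± 0.62 (SE, n = 3 per group), from a mean signal of 12.2 ± 8.28 (SD) to 9309 ± 4885 (adjusted p = 3.93e-06). The glutathione S-transferases Gstm3 and Gsta3 rose by 5.84 ± 0.43 and 5.34 ± 0.17, and the conjugate exporter Abcc3 by 5.65 ± 0.29. Stac3 showed the deepest drop of the named genes, with a change of -7.06 ± 0.43, followed by the carbonic anhydrase Car3 with -5.37 ± 0.70, Dhrs7l1 with -5.31 ± 0.90 and the fatty acid desaturase Scd with -4.96 ± 0.62. Rises of 5.42 ± 0.93 for the acyl-CoA thioesterase Acot1, 5.25 ± 0.26 for Nol3, 5.09 ± 0.22 for the gamma-glutamyl transferase Ggt1 and 4.95 ± 0.44 for the glutathione peroxidase Gpx2 completed the 8 largest. The signals of Acot1 at 1500 mg/kg were 1554, 252.2 and 12670 for replicates 1, 2 and 3, and its change was 3.99 without PBO 1500 replicate 3. Without that animal the change of Car3 was -4.24 and that of Dhrs7l1 -6.62. Nrep, the lysyl oxidase Lox, the taurine transporter Slc6a6 and the complement gene C6 fell, with changes of -4.95, -3.83, -3.82 and -3.35. In each of these genes the 3 dosed animals lay on 1 side of the 3 controls, as the naming rule required; chance separates 3 from 3 animals in 10% of genes.

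Targets of the nuclear receptors CAR and PXR, which govern drug metabolism, were higher at 1500 mg/kg. Of 20 measured members 13 rose and none fell (15 rose when adjusted over the list alone), for example Aldh1a1 (3.76 ± 0.16) and the carboxylesterase Ces2c (4.89 ± 0.20). Their median change was 1.16, with a camera adjusted p = 5.93e-11 (adjusted p = 0.0281 with an estimated correlation). Among targets of NRF2, the regulator of the antioxidant response, 16 of 23 rose and none fell (17 adjusted over the list alone), including glutathione reductase Gsr (2.42 ± 0.17) and malic enzyme Me1 (2.36 ± 0.17). Camera gave that list an adjusted p = 3.36e-14 (adjusted p = 0.0139 with an estimated correlation). The glutathione S-transferase list had 11 rises and 3 falls among 19 (11 and 3 adjusted over the list alone), Mgst2 rising by 1.26 ± 0.10, with a camera adjusted p = 5.67e-05 (adjusted p = 0.12 with an estimated correlation). Of 31 targets of PPARalpha, the receptor that drives fatty acid oxidation, 18 rose and none fell (19 adjusted over the list alone), among them Vnn1 (3.23 ± 0.19), Ech1 (1.75 ± 0.15) and Hadhb (1.05 ± 0.09). The camera test of that list gave an adjusted p = 1.6e-09 (adjusted p = 0.192 with an estimated correlation), and its per-array medians were 0.56, 0.48 and 1.28 for replicates 1, 2 and 3. Markers of altered hepatic foci and tumours had 5 rises and no fall among 11 (5 and 2 adjusted over the list alone), with Ephx1 at 1.29 ± 0.12 and Akr7a3 at 2.60 ± 0.27 (camera adjusted p = 0.000901, adjusted p = 0.098 with an estimated correlation). In cholesterol synthesis and uptake 6 of 21 members rose and 1 fell (8 and 1 adjusted over the list alone), the squalene epoxidase Sqle by 1.61 ± 0.19 and Msmo1 by 1.21 ± 0.24. That call, with a camera adjusted p = 0.012, was lost without PBO 1500 replicate 2 (adjusted p = 0.0734) and had an adjusted p = 0.567 with an estimated correlation. AhR targets, the genes of the aryl hydrocarbon receptor, were not called as a list (camera adjusted p = 0.0717), with 2 rises among 5 (2 adjusted over the list alone). Cell cycle genes were not called either (camera adjusted p = 0.0611), with 3 rises and no fall among 34 (2 rises adjusted over the list alone) and a median change of 0.28 (0.14 without PBO 1500 replicate 3). Abcc3 and Ephx1 belong to the CAR/PXR, NRF2 and foci lists, and Nqo1 to the AhR, NRF2 and foci lists. Akr7a3 and Gstp1 belong to the NRF2 and foci lists, and Aldh3a1 to the AhR and foci lists. Other lists share genes too. For example, Gstp1 is also a glutathione S-transferase, Me1 is in the NRF2 and fatty acid synthesis lists, and Cyp3a2 in the CAR/PXR and male-predominant lists. These counts are therefore not independent, and the foci call is not separate from the others.

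Secreted hepatocyte proteins were lower at 1500 mg/kg, with 8 of 19 members falling and none rising (11 falls adjusted over the list alone), for example the apolipoprotein Apoa5 (-1.19 ± 0.12) and Igfals (-2.37 ± 0.47, and -1.55 without PBO 1500 replicate 3). That list had a camera adjusted p = 0.000346 (adjusted p = 0.476 with an estimated correlation). Genes expressed mainly in male liver had 5 falls among 8 (7 adjusted over the list alone), including the steroid hydroxylase Cyp2c11 (-2.26 ± 0.35) and Mup5 (-1.16 ± 0.13). Their list had a camera adjusted p = 0.000901 (adjusted p = 0.137 with an estimated correlation). In gluconeogenesis and amino acid catabolism 7 of 18 fell and 1 rose (8 and 1 adjusted over the list alone), with Kynu at -1.40 ± 0.10 and the betaine methyltransferase Bhmt at -1.12 ± 0.13 (camera adjusted p = 0.0147, adjusted p = 0.12 with an estimated correlation). Markers of other cell types moved too. Erythroid markers had 3 falls among 5 (3 adjusted over the list alone), the globin Hbb by -1.70 ± 0.23 and Alas2 by -1.59 ± 0.23 (camera adjusted p = 0.00629, adjusted p = 0.12 with an estimated correlation). Macrophage markers had 3 falls among 11 (6 adjusted over the list alone), with a camera adjusted p = 0.00491 (adjusted p = 0.484 with an estimated correlation), and per-array medians of -0.15, -0.80 and -2.54 for replicates 1, 2 and 3. T and NK cell markers had 3 falls among 5 (4 adjusted over the list alone), Gzmb by -1.78 ± 0.38, with a camera adjusted p = 0.0387 (adjusted p = 0.265 with an estimated correlation). That call was lost without control replicate 1 or 2 or PBO 1500 replicate 2 or 3, with adjusted p of 0.0996, 0.0834, 0.0602 and 0.0513. Of the macrophage genes that fell, Clec4f (-1.61 ± 0.39, adjusted p = 0.0132) lost its call without control replicate 1 (adjusted p = 0.0501), and its change was -1.02 without PBO 1500 replicate 3. Fatty acid synthesis genes were not called as a list (camera adjusted p = 0.0561), although 6 of 18 fell and 2 rose (8 and 2 adjusted over the list alone), the lipogenic regulator Srebf1 by -2.28 ± 0.32.

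Of the other genes fixed in advance, the cytochrome P450 Cyp3a23-3a1 rose by 0.74 ± 0.10, the fatty acid hydroxylase Cyp4a1 by 1.15 ± 0.23 and the quinone reductase Nqo1 by 1.62 ± 0.24 at 1500 mg/kg. The stress gene Gadd45b rose by 3.18 ± 1.01 (adjusted p = 0.0472), and its call was lost without control replicate 1, 2 or 3 or PBO 1500 replicate 3, with adjusted p of 0.153, 0.103, 0.0663 and 0.0821. Its change was 1.60 without that dosed animal. Cyp1a2 (0.47 ± 0.27, adjusted p = 0.261) passed the threshold without PBO 1500 replicate 3 (adjusted p = 0.00312), and the placental transferase Gstp1 (0.88 ± 0.40, adjusted p = 0.154) without PBO 1500 replicate 2 (adjusted p = 0.0385). The bile acid enzyme Cyp7a1 (-0.92 ± 0.76), the cell cycle genes Cdkn1a (-0.03 ± 0.47), Ccnd1 (0.49 ± 0.81) and Mki67 (0.08 ± 0.36), and albumin, Alb (0.06 ± 0.15), did not pass. Among 18625 probe sets tested, 3228 passed, 1504 higher and 1724 lower, of which 550 and 693 changed by at least 2-fold. Scaling each array to a common median shifted all changes by 0.111 and gave 1905 higher and 1203 lower, so the share of higher calls went from 46.6% to 61.3% and changes near that size have no settled direction. The count was 2134 without control replicate 1 and 2032 without control replicate 3, and 1550 with only the arrays of both groups in the fit.

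**Figure D1:**
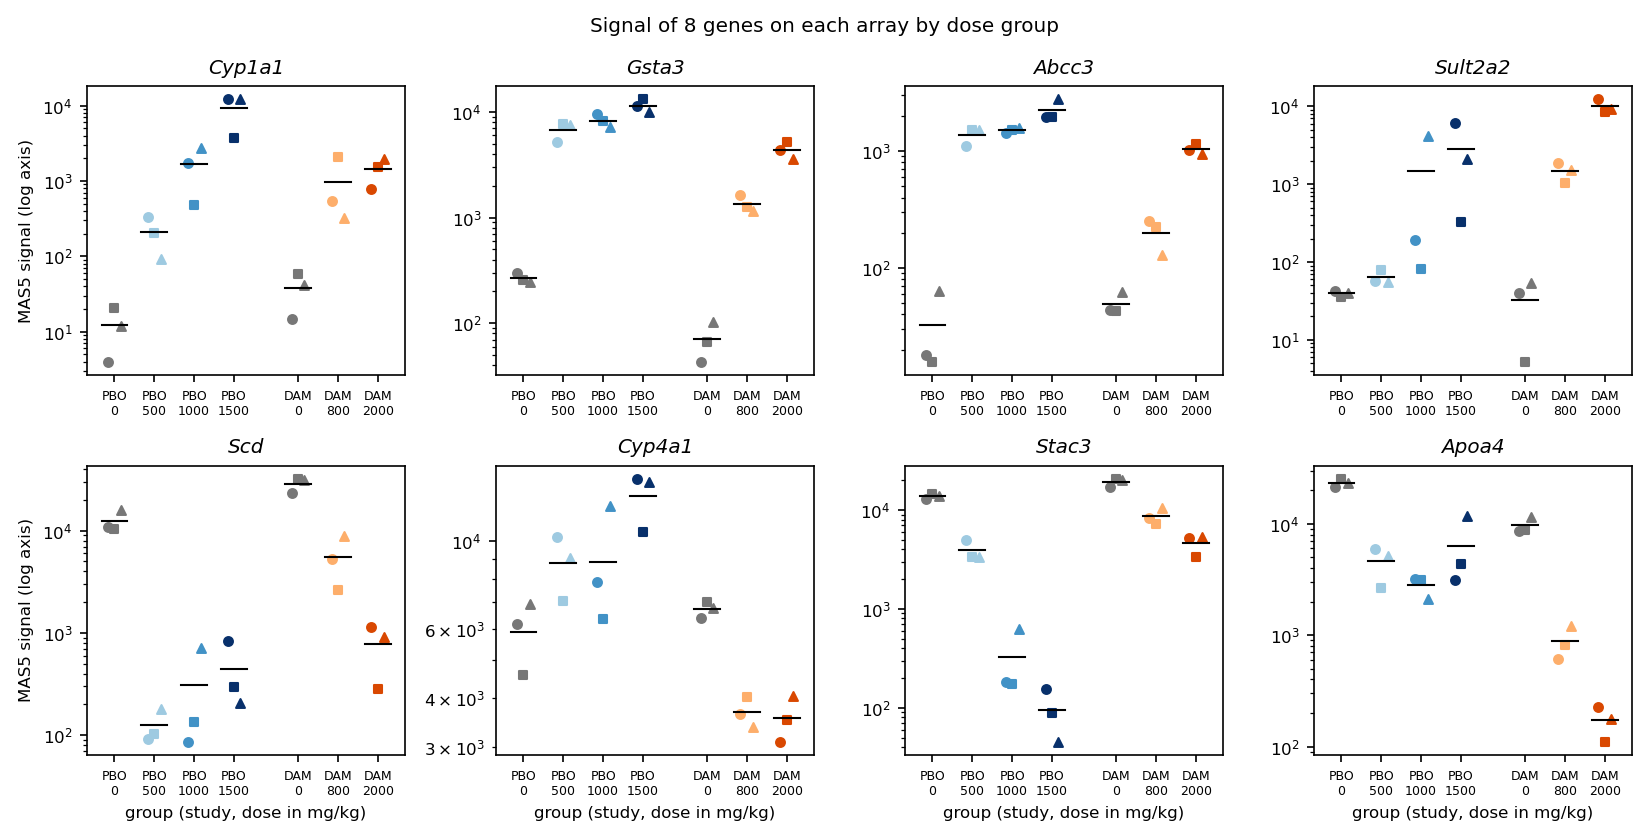
MAS5 signal of 8 genes on each array (log axis) against dose group in mg/kg, with circles, squares and triangles for replicates 1, 2 and 3 and a bar at the mean of 3 animals. Cyp1a1 stood at a mean of 12.2 in PBO controls and 9309 at 1500 mg/kg, and Cyp4a1 was higher at PBO 1500 mg/kg and lower at both DAM doses than in their controls.

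At 500 mg/kg of PBO Abcc3 rose by 4.97 ± 0.29, Gsta3 by 4.57 ± 0.17, Ces2c by 4.25 ± 0.20, the retinal dehydrogenase Aldh1a1 by 3.48 ± 0.16 and Ugt2b1 by 3.12 ± 0.20. Scd had the deepest drop, with a change of -6.48 ± 0.62, and the fatty acid binding protein Fabp5 had -2.49 ± 0.24. Slc6a6 (-3.36 ± 0.56), the phosphatase Cdkn3 (-2.85 ± 0.54) and Apoa4 (-2.42 ± 0.40) also fell, with calls that single arrays decided. Without control replicate 1, 2 or 3, Slc6a6 had an adjusted p of 0.101, 0.0685 and 0.0583, Cdkn3 of 0.117, 0.137 and 0.151, and Apoa4 of 0.0678, 0.0829 and 0.0665. Without PBO 500 replicate 2, Cdkn3 had 0.151 and Apoa4 0.0867, and without replicate 3, Slc6a6 had 0.057 and Cdkn3 0.119. CAR/PXR targets had 7 rises among 20 (10 adjusted over the list alone), NRF2 targets 5 among 23 (11 adjusted over the list alone) and glutathione S-transferases 5 among 19 (10 adjusted over the list alone), with no fall. PPARalpha targets had 4 rises among 31 (8 adjusted over the list alone), Vnn1 by 1.60 ± 0.19, with a camera adjusted p = 5.03e-11 (adjusted p = 0.166 with an estimated correlation). Cholesterol synthesis and uptake was called higher with 0 rises among 21 (1 adjusted over the list alone), with a camera adjusted p = 3.84e-07 (adjusted p = 0.306 with an estimated correlation). AhR targets were called higher with 0 rises among 5 (3 adjusted over the list alone), with a camera adjusted p = 0.0128 (adjusted p = 0.104 with an estimated correlation). In all 14 lists were called, 9 higher and 5 lower. The calls that held were those of the CAR/PXR and NRF2 targets (both with adjusted p = 0.00395 with an estimated correlation), the transferases (adjusted p = 0.00652 with an estimated correlation) and the foci markers. The last had 4 rises among 11, 5 adjusted over the list alone, with an adjusted p = 0.00607 with an estimated correlation. Cell cycle genes were lower as a list, with 1 of 34 falling (16 adjusted over the list alone), Cdkn3, a median change of -0.79 and a camera adjusted p = 3.88e-09 (adjusted p = 0.178 with an estimated correlation). Of markers of other cell types, erythroid markers were called lower with 0 falls among 5 (1 adjusted over the list alone), with a camera adjusted p = 0.0308 (adjusted p = 0.169 with an estimated correlation). That call was lost without control replicate 1 or 3 or PBO 500 replicate 2 or 3 (adjusted p of 0.0594, 0.156, 0.0618 and 0.072). Cholangiocyte markers were called higher with 0 rises among 5 (1 adjusted over the list alone), with a camera adjusted p = 0.0261 (adjusted p = 0.169 with an estimated correlation), lost without control replicate 1 or 2 or PBO 500 replicate 1 (adjusted p of 0.0594, 0.117 and 0.103). Cyp3a23-3a1 rose by 0.82 ± 0.10, whereas Cyp1a1 (2.89 ± 0.62, adjusted p = 0.0707), Nqo1 (1.14 ± 0.24, adjusted p = 0.0679) and Cyp1a2 (0.73 ± 0.27, adjusted p = 0.363) passed without PBO 1500 replicate 3 (adjusted p of 0.0252, 0.0263 and 0.0245). Cyp2c11 (-0.05), Cyp4a1 (0.58), Cyp7a1 (0.07), Gstp1 (0.53), Gadd45b (-0.07), Cdkn1a (0.14), Ccnd1 (-1.50), Mki67 (-0.94) and Alb (0.13) did not pass. Altogether 89 probe sets passed, 65 higher and 24 lower (97 and 19 with median scaling, a share of 83.6% against 73.0%). The count was 371 without PBO 1500 replicate 3, with all 89 shared, 52 without control replicate 1 or 2, and 54 and 59 without PBO 500 replicate 1 and 2.

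At 1000 mg/kg Cyp1a1 rose by 5.61 ± 0.62, Abcc3 by 5.11 ± 0.29, Gsta3 by 4.88 ± 0.17, Ces2c by 4.55 ± 0.20 and the medium-chain acyl-CoA synthetase Acsm2 by 3.76 ± 0.31. Scd (-5.76 ± 0.62), Stac3 (-5.56 ± 0.43), Slc6a6 (-4.69 ± 0.56) and Lox (-4.18 ± 0.59) fell. Dhrs7l1 (-3.97 ± 0.90, adjusted p = 0.032) fell as well, with its call lost without control replicate 1, 2 or 3 or PBO 1000 replicate 1 or 3 (adjusted p of 0.104, 0.121, 0.0705, 0.0973 and 0.139). CAR/PXR targets had 9 rises among 20 (11 adjusted over the list alone) and NRF2 targets 10 among 23 (13 adjusted over the list alone), both with adjusted p = 0.00642 with an estimated correlation. Cholesterol synthesis and uptake had 5 rises among 21 (10 adjusted over the list alone), Sqle by 1.29 ± 0.19, with a camera adjusted p = 7.25e-08 (adjusted p = 0.267 with an estimated correlation). Gluconeogenesis and amino acid catabolism had 6 falls among 18 (7 adjusted over the list alone), including Bhmt (-1.06 ± 0.13) and Kynu (-0.70 ± 0.10), with an adjusted p = 0.042 with an estimated correlation. Erythroid markers had 1 fall among 5 (3 adjusted over the list alone), a median change of -0.90 and a camera adjusted p = 0.00398 (adjusted p = 0.0913 with an estimated correlation). AhR targets had 2 rises among 5 (3 adjusted over the list alone), with a camera adjusted p = 0.0142 (adjusted p = 0.0913 with an estimated correlation). Cell cycle genes were called lower with 1 fall among 34 (14 falls and 1 rise adjusted over the list alone), a median change of -0.79 and a camera adjusted p = 0.000286 (adjusted p = 0.399 with an estimated correlation). In all 15 lists were called, 9 higher and 6 lower, and 5 with an estimated correlation. Nqo1 rose by 1.82 ± 0.24 and Cyp3a23-3a1 by 0.80 ± 0.10. Cyp1a2 (0.75 ± 0.27, adjusted p = 0.188) passed without PBO 1500 replicate 3 (adjusted p = 0.00814). Cyp2c11 (-0.87), Cyp4a1 (0.55), Cyp7a1 (0.38), Gstp1 (-0.05), Gadd45b (0.67), Cdkn1a (-0.50), Ccnd1 (-1.21), Mki67 (-0.97) and Alb (-0.01) did not pass. Of the 581 probe sets that passed, 351 were higher and 230 lower. Median scaling shifted all changes by 0.102 and gave 538 higher and 150 lower, a share of 78.2% against 60.4%. The count was 1448 without PBO 1500 replicate 3, with 580 shared, 296, 263 and 282 without control replicate 1, 2 and 3, and 255, 329 and 267 without PBO 1000 replicate 1, 2 and 3.

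The linear trend over the 4 PBO doses, per step of 500 mg/kg, was steepest for Cyp1a1 (2.74 ± 0.18), Gstm3 (1.80 ± 0.18), Nol3 (1.74 ± 0.08), the bile acid sulfotransferase Sult2a2 (1.72 ± 0.36) and Abcc3 (1.71 ± 0.30). Falling trends were steepest for Stac3 (-2.49 ± 0.17), Ugt2b (-2.14 ± 0.66), Dhrs7l1 (-1.93 ± 0.30), Car3 (-1.69 ± 0.35) and Nrep (-1.59 ± 0.19). These slopes assume equal steps, and departure from a straight line was not tested. Abcc3 had most of its rise at 500 mg/kg already, and the changes of Cyp3a23-3a1 were alike at each PBO dose. Car3 and Cyp2c11 fell mainly above 500 mg/kg. The Ugt2b trend (adjusted p = 0.0382) was lost without any 1 of control replicates 1 to 3, PBO 500 replicates 1 to 3 and PBO 1500 replicates 1 and 2, with adjusted p of 0.0543 to 0.118. Its 12 signals fell into a high range from 17560 upward and a low range up to 62.5, with 3 animals low at 1000 and 1500 mg/kg. Cyp2c11 fell along the doses by 0.76 ± 0.13 per step, and Cyp4a1 and Nqo1 rose by 0.34 ± 0.08 and 0.55 ± 0.11. Cyp3a23-3a1 (0.22 ± 0.06, adjusted p = 0.0281) lost its call without control replicate 1, 2 or 3 (adjusted p of 0.0946, 0.0948 and 0.0803). Gadd45b (1.03 ± 0.34, adjusted p = 0.0487) lost it without any 1 array other than control replicate 3 and PBO 1500 replicate 2 (adjusted p of 0.0528 to 0.106), and its trend was 0.53 without PBO 1500 replicate 3. Cyp1a2 (0.14 ± 0.10) passed without PBO 1500 replicate 3 (adjusted p = 0.0109). Cyp7a1, Gstp1, Cdkn1a, Ccnd1, Mki67 and Alb did not pass. The trend passed the threshold for 3122 probe sets, 1475 higher and 1647 lower (1876 and 1051 with median scaling, a share of 64.1% against 47.2%). Between 1500 and 500 mg/kg, Cyp1a1 (5.33 ± 0.62), Acot1 (5.12 ± 0.93), the profilin Pfn2 (3.37 ± 0.23) and Nol3 (3.19 ± 0.26) were higher at the higher dose. Car3 (-5.42 ± 0.70), Stac3 (-5.23 ± 0.43), Dhrs7l1 (-4.69 ± 0.90), Nrep (-4.39 ± 0.31) and the monooxygenase Fmo1 (-3.15 ± 0.63) were lower. Without PBO 1500 replicate 3 the differences of Acot1, Car3 and Dhrs7l1 were 3.69, -4.28 and -6.00, and with only the arrays of both groups Acot1, Dhrs7l1 and Fmo1 did not pass (adjusted p of 0.0802, 0.0716 and 0.0983). Sult2a2 (4.38 ± 1.16, adjusted p = 0.0388) lost its call without PBO 500 replicate 1, 2 or 3 or PBO 1500 replicate 1 or 3 (adjusted p of 0.107, 0.0991, 0.103, 0.103 and 0.0704). Cyp2c11 was lower (-2.21 ± 0.35). Gadd45b (3.25 ± 1.01) and Ccnd1 (1.98 ± 0.81) passed without PBO 1500 replicate 2 (adjusted p of 0.0186 and 0.011). The other fixed genes did not pass. Here 1370 probe sets passed, 699 higher and 671 lower, and 663, 613 and 811 without PBO 500 replicate 1, 2 and 3.

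The PBO doses share 3 control arrays. Of the 89 probe sets past the threshold at 500 mg/kg, 83 also passed at 1500 mg/kg in the same direction, against 5.25 higher and 2.22 lower for independent lists. Of the 581 at 1000 mg/kg, 529 did, against 28.3 and 21.3 for independent lists. The 20 simulations of unchanged groups gave a mean of 0 shared calls. That mean is no baseline for these counts, since unchanged data give no calls that could be shared. Across probe sets, which are not independent replicates, changes at 1000 and 1500 mg/kg correlated with r = 0.703 (0.5 in the simulation), and their covariance was 0.207 beside a simulated 0.054. For 500 and 1500 mg/kg r was 0.574 (0.501 simulated) and the covariance 0.143 beside 0.0538. Part of the excess over independent lists may come from the shared controls, which are too few to be split. The simulated r and covariance already hold the shared controls, with values drawn independently for each probe set.

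At the highest dose of DAM, after 28 days, Sult2a2 rose by 7.83 ± 0.35 (adjusted p = 7.29e-08), from a mean signal of 32.8 ± 24.9 (SD) to 10010 ± 2092 in 3 animals each. Gsta3 rose by 5.71 ± 0.22, Cyp1a1 by 4.73 ± 0.55, Gpx2 by 4.64 ± 0.21, the sterol exporter Abcg5 by 4.20 ± 0.35, Sult2a6 by 4.08 ± 0.12, Abcc3 by 4.03 ± 0.21 and Ggt1 by 3.63 ± 0.14. The apolipoprotein Apoa4 had the deepest drop (-5.73 ± 0.25), followed by Scd (-5.38 ± 0.46), the transcriptional repressor Bcl6 (-3.83 ± 0.38) and Spin2b (-3.56 ± 0.32). The rhythmic deadenylase Noct (-3.55 ± 0.28), serine dehydratase Sds (-3.42 ± 0.59), the kinase Sgk1 (-3.19 ± 0.39) and the nuclear receptor Nr0b2 (-2.58 ± 0.19) also fell. In each of these genes too the dosed animals and the controls did not overlap, as the naming rule required, so this separation is no result of its own.

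CAR/PXR targets had 14 rises and no fall among 19 at 2000 mg/kg of DAM (15 adjusted over the list alone), including the drug exporter Abcb1a (3.06 ± 0.14), Ces2c (3.14 ± 0.14) and Aldh1a1 (3.44 ± 0.20). Their camera test gave an adjusted p = 4.45e-15 (adjusted p = 0.141 with an estimated correlation). NRF2 targets had 12 rises and no fall among 23 (14 and 1 adjusted over the list alone), with a camera adjusted p = 6.38e-10 (adjusted p = 0.118 with an estimated correlation). Cholesterol synthesis and uptake had 13 rises and 1 fall among 21 (15 and 1 adjusted over the list alone), the isomerase Idi1 rising by 1.84 ± 0.28 and Sqle by 2.12 ± 0.35, while Insig1, which restrains sterol synthesis, fell (-1.07 ± 0.17). The camera adjusted p of that list was 4.12e-06 (adjusted p = 0.474 with an estimated correlation). Glutathione S-transferases had 9 rises and 1 fall among 19 (13 and 1 adjusted over the list alone), Gstm3 by 2.80 ± 0.22 (camera adjusted p = 5.95e-07, adjusted p = 0.266 with an estimated correlation). Conjugating UDP-glucuronosyltransferases and sulfotransferases had 6 rises and 2 falls among 13 (7 and 4 adjusted over the list alone), Ugt2b1 by 1.89 ± 0.17 (camera adjusted p = 0.00896, adjusted p = 0.304 with an estimated correlation). Foci and tumour markers had 5 rises and 2 falls among 10 (5 and 2 adjusted over the list alone), Ephx1 by 0.97 ± 0.09 (camera adjusted p = 0.00208, adjusted p = 0.141 with an estimated correlation). AhR targets had 2 rises among 5 (3 adjusted over the list alone), Nqo1 by 1.26 ± 0.11 and Cyp1a1, with a camera adjusted p = 0.00356 (adjusted p = 0.266 with an estimated correlation).

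Fatty acid synthesis genes were lower at 2000 mg/kg of DAM, with 9 falls and 1 rise among 17 (12 and 3 adjusted over the list alone), including Srebf1 (-1.76 ± 0.12), Thrsp (-1.47 ± 0.15) and the acetyl-CoA carboxylase Acaca (-1.16 ± 0.14). The list had a camera adjusted p = 3.01e-05 (adjusted p = 0.266 with an estimated correlation). Gluconeogenesis and amino acid catabolism had 6 falls and 2 rises among 18 (10 and 2 adjusted over the list alone), the tyrosine aminotransferase Tat by -2.35 ± 0.20 and Hal by -1.55 ± 0.18 (camera adjusted p = 0.00195, adjusted p = 0.474 with an estimated correlation). Circadian clock genes had 6 falls among 12 (6 adjusted over the list alone), Per1 by -2.36 ± 0.41 and Npas2 by -0.57 ± 0.09 (camera adjusted p = 0.00896, adjusted p = 0.304 with an estimated correlation). Macrophage markers had 2 falls among 11 (2 adjusted over the list alone), Cd68 by -0.78 ± 0.11 (camera adjusted p = 0.0026, adjusted p = 0.561 with an estimated correlation). Stellate cell and fibroblast markers had 3 falls among 14 (4 adjusted over the list alone), the retinol esterifying Lrat by -0.63 ± 0.12. That call, with a camera adjusted p = 0.00794, was lost without DAM control replicate 3 (adjusted p = 0.127) and had an adjusted p = 0.474 with an estimated correlation. PPARalpha targets were not called (camera adjusted p = 0.622), with 2 rises and 4 falls among 30 (2 and 4 adjusted over the list alone), among them Cyp4a1 (-0.92 ± 0.10) and the lipid droplet protein Plin2 (-0.66 ± 0.08). Bile acid synthesis and transport was not called either (camera adjusted p = 0.906), with 6 rises and 6 falls among 18 (7 and 6 adjusted over the list alone), Abcg8 rising by 3.57 ± 0.34 and Cyp7a1 falling (-2.52 ± 0.35). Its median was -0.03, while its mean (0.20) and test pointed up.

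Of the other genes fixed in advance, Cyp3a23-3a1 rose by 0.63 ± 0.09 and Gadd45b by 1.52 ± 0.33 at 2000 mg/kg of DAM. Cyp2c11 (-0.35 ± 0.12, adjusted p = 0.0721) passed without DAM control replicate 1 (adjusted p = 0.0408). Gstp1 (0.34 ± 0.20, adjusted p = 0.311) passed without DAM 2000 replicate 1 (adjusted p = 0.0104), and Alb (0.28 ± 0.12, adjusted p = 0.167) without DAM control replicate 2 (adjusted p = 0.0135). Cyp1a2 (0.14 ± 0.15), Cdkn1a (0.29 ± 0.15), Ccnd1 (-0.21 ± 0.14) and Mki67 (-0.64 ± 0.43) did not pass. In all, 2296 of 18625 probe sets passed, 1158 higher and 1138 lower, of which 174 and 211 changed by at least 2-fold. With median scaling, which shifted all changes by 0.0928, 1620 were higher and 657 lower, a share of 71.2% against 50.4%. The count was 1492 without DAM 2000 replicate 2.

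**Figure D2:**
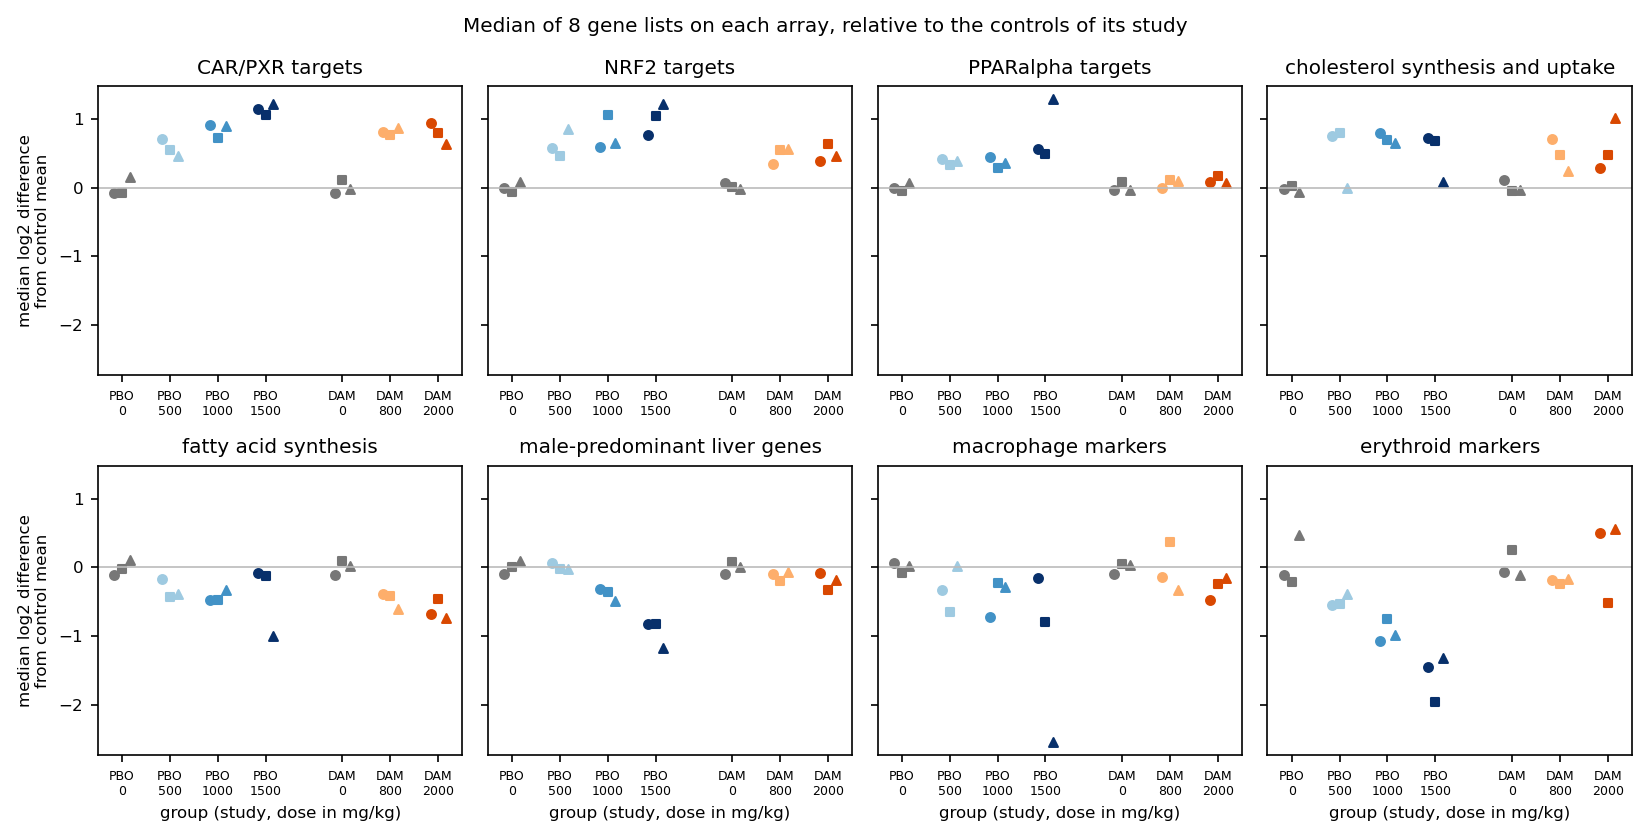
Median log2 difference from the study's control mean over the members of 8 gene lists, for each array, against dose group in mg/kg, with circles, squares and triangles for replicates 1, 2 and 3. CAR/PXR targets lay above the controls on every dosed array, and macrophage markers of PBO 1500 replicate 3 stood at -2.54.

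At 800 mg/kg of DAM Sult2a2 rose by 5.06 ± 0.35, Abcg5 by 4.23 ± 0.35, Gsta3 by 4.03 ± 0.22, Cyp1a1 by 3.85 ± 0.55 and Abcg8, the partner of Abcg5, by 3.58 ± 0.34. Apoa4 (-3.48 ± 0.25), Spin2b (-2.76 ± 0.32), Scd (-2.52 ± 0.46) and Slc6a6 (-2.05 ± 0.18) fell. Sds (-2.96 ± 0.59, adjusted p = 0.0149) fell too, with its call lost without DAM control replicate 3 or DAM 800 replicate 1 or 3 (adjusted p of 0.0562, 0.0583 and 0.0594). CAR/PXR targets had 13 rises among 19 (14 adjusted over the list alone), Abcb1a by 2.68 ± 0.14, with a camera adjusted p = 8.34e-23 (adjusted p = 0.0684 with an estimated correlation). Fatty acid synthesis had 8 falls and 1 rise among 17 (9 and 1 adjusted over the list alone), Srebf1 by -1.03 ± 0.12, with a camera adjusted p = 1.05e-05 (adjusted p = 0.213 with an estimated correlation). AhR targets were not called (camera adjusted p = 0.0706), with 2 rises among 5 (2 adjusted over the list alone). In all 11 lists were called, 8 higher and 3 lower, and 0 with an estimated correlation. Cyp4a1 (-0.86 ± 0.10) was lower and Nqo1 (0.81 ± 0.11) and Cyp3a23-3a1 (0.54 ± 0.09) higher. Gadd45b (1.62 ± 0.33, adjusted p = 0.0158) lost its call without DAM control replicate 2 or DAM 800 replicate 1 or 2 (adjusted p of 0.0554, 0.0583 and 0.0571). Cdkn1a (0.61 ± 0.15, adjusted p = 0.0352) lost it without DAM control replicate 1 or 3 or DAM 800 replicate 1, 2 or 3 (adjusted p of 0.104, 0.0581, 0.0862, 0.112 and 0.0966). Alb (0.28 ± 0.12) passed without DAM control replicate 2 (adjusted p = 0.0324), and Cyp1a2, Cyp2c11, Cyp7a1, Gstp1, Ccnd1 and Mki67 did not pass. Of the 705 probe sets that passed, 403 were higher and 302 lower (453 and 173 with median scaling, a share of 72.4% against 57.2%). The count was 459 without DAM control replicate 1, and 445, 433 and 382 without DAM 800 replicate 1, 2 and 3. Of these 705, 618 also passed at 2000 mg/kg in the same direction, against 25.1 higher and 18.5 lower for independent lists. Changes at both doses correlated across probe sets with r = 0.734 (0.499 simulated) and a covariance of 0.096 beside 0.0241. The simulated values already hold the 3 shared controls, from which part of the shared calls may also come.

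Between 2000 and 800 mg/kg of DAM, Onecut1 (2.90 ± 0.33) and Foxa2 (1.95 ± 0.22), both hepatocyte transcription factors, were higher at the higher dose, as were Sult2a2 (2.77 ± 0.35), the cytokine signalling inhibitor Cish (2.60 ± 0.29) and Abcc3 (2.33 ± 0.21). Bcl6 (-4.17 ± 0.38), Zfp354a (-2.89 ± 0.28), Scd (-2.86 ± 0.46), Nr0b2 (-2.50 ± 0.19) and Apoa4 (-2.25 ± 0.25) were lower. Cyp7a1 (-1.74 ± 0.35, adjusted p = 0.0336) lost its call without DAM 800 replicate 2 or 3 or DAM 2000 replicate 1 or 2 (adjusted p of 0.143, 0.0965, 0.0597 and 0.128), and the other fixed genes did not pass. Here 207 probe sets passed, 73 higher and 134 lower, and 121, 123 and 125 without DAM 800 replicate 1, DAM 800 replicate 2 and DAM 2000 replicate 2.

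The effects of PBO at 1500 mg/kg and DAM at 2000 mg/kg were compared across studies that also differ in strain, route, duration and tissue preservation, so the compound cannot be separated from these. Among 17157 probe sets tested in both, 544 were higher and 471 lower with both compounds, against 96.6 and 108 for independent lists, and 25 passed in opposite directions. Without the intensity trend 608 passed in the same direction, against 1015 in the main fit. Gsta3, Gpx2, Abcc3, Ggt1 and Scd were among those that moved alike. The changes correlated across probe sets with r = 0.487. The difference of effects, PBO minus DAM, was highest for Noct (5.12 ± 0.59), Pfn2 (3.72 ± 0.31), Apoa4 (3.62 ± 0.54) and Slc66a3 (3.60 ± 0.35), and lowest for Car3 (-5.22 ± 0.81), Stac3 (-4.98 ± 0.52), Dhrs7l1 (-4.30 ± 1.04), Nrep (-4.16 ± 0.38) and the neprilysin gene Mme (-4.01 ± 0.56). For Cyp1a1 (3.50 ± 0.94, adjusted p = 0.037) the difference lost its call without PBO control replicate 1 or 3, PBO 1500 replicate 1 or 3, DAM control replicate 2 or 3 or DAM 2000 replicate 1 or 2, with adjusted p of 0.0562 to 0.107. For Dhrs7l1 (adjusted p = 0.0209) it was lost without PBO control replicate 2 or DAM 2000 replicate 3 (adjusted p of 0.0522 and 0.0535). Without PBO 1500 replicate 3 the differences of Car3 and Dhrs7l1 were -4.09 and -5.62. Cyp4a1 (2.07 ± 0.28) and Cyp2c11 (-1.91 ± 0.42) also differed, and the other fixed genes did not pass. Cyp4a1 was 1 of 19 genes called in opposite directions with a difference past the threshold, of which 6 were higher and 13 lower with PBO.

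As lists, PPARalpha targets differed with a median of 0.68 in favour of PBO (0.40 without PBO 1500 replicate 3), with 9 of 30 differing (15 adjusted over the list alone) and a camera adjusted p = 1.28e-11 (adjusted p = 0.143 with an estimated correlation). NRF2 targets differed with a median of 0.46, with 6 of 23 differing (9 higher and 1 lower adjusted over the list alone), a camera adjusted p = 8.99e-07 and adjusted p = 0.0432 with an estimated correlation. Erythroid markers (-1.86, adjusted p = 0.0537 with an estimated correlation), secreted hepatocyte proteins (-0.44, adjusted p = 0.507 with an estimated correlation) and male-predominant genes (-0.52, adjusted p = 0.218 with an estimated correlation) were lower with PBO. The difference passed the threshold for 914 of 18625 probe sets, 399 higher and 515 lower. The count was 1425 without PBO 1500 replicate 2, 609, 553 and 553 without DAM control replicate 1, 2 and 3, and 502 and 588 without DAM 2000 replicate 1 and 3.

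**Figure D3:**
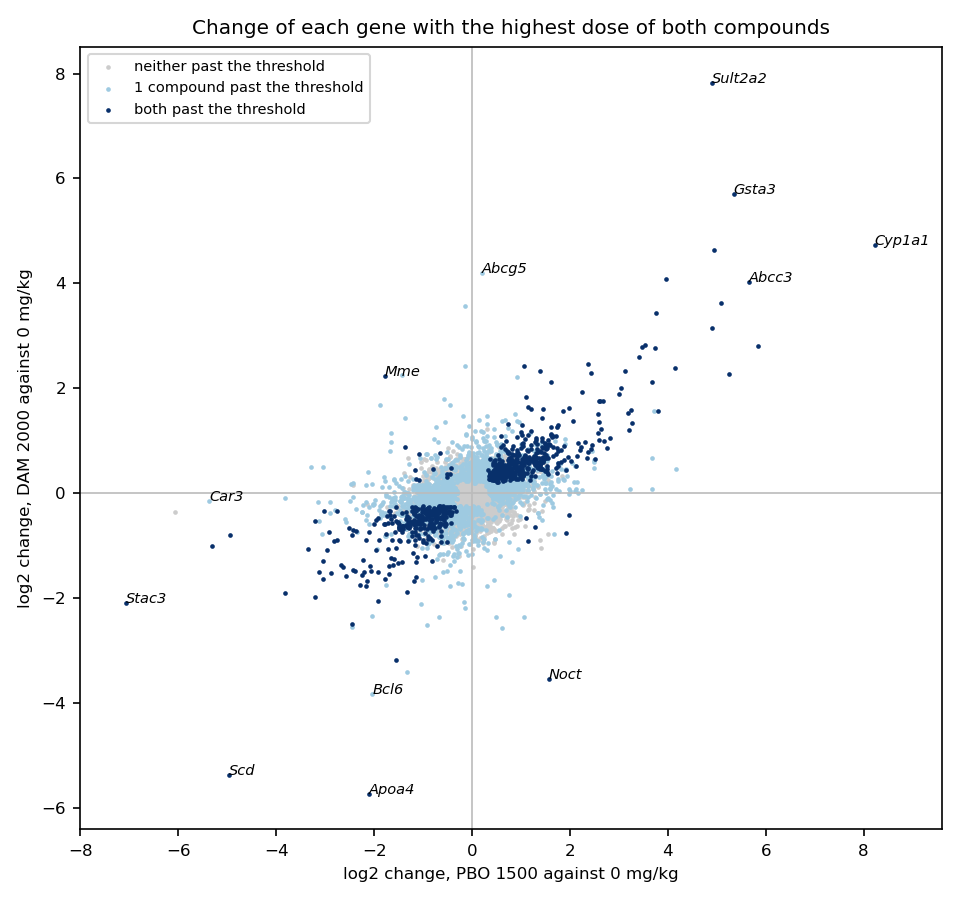
Log2 change of 9835 genes at PBO 1500 against 0 mg/kg (horizontal axis) and DAM 2000 against 0 mg/kg (vertical axis), coloured by whether the change passed the threshold with neither, 1 or both compounds. Gsta3 and Abcc3 were high with both, Scd was low with both, and Noct lay at 1.57 with PBO and -3.55 with DAM.

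RNA quality was read from control probe sets at both ends of the Actb and Gapdh transcripts. The log2 ratio of 3' to 5' signal ranged from 1.25 to 1.66 for Actb and from 0.10 to 0.25 for Gapdh in the PBO study, and from 2.48 to 3.29 and from 0.61 to 1.01 in the DAM study. In PBO animals the Actb ratio was lower than in controls at 500, 1000 and 1500 mg/kg, with differences of -0.14, -0.30 and -0.21 and a two-sided exact permutation p of 0.1 for each. At 800 and 2000 mg/kg of DAM the Actb differences were -0.34 and -0.03, with p of 0.2 and 0.9, so the largest difference was not in the PBO study. A p of 0.1 is the smallest that 3 against 3 animals allow, and Benjamini-Hochberg adjustment over 10 comparisons left no value below 0.333. On the first principal component of the PBO study, PBO 1500 replicate 3 stood at 90.5 and the other arrays of its group at 29.9 and 26.7.

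**Figure D4:**
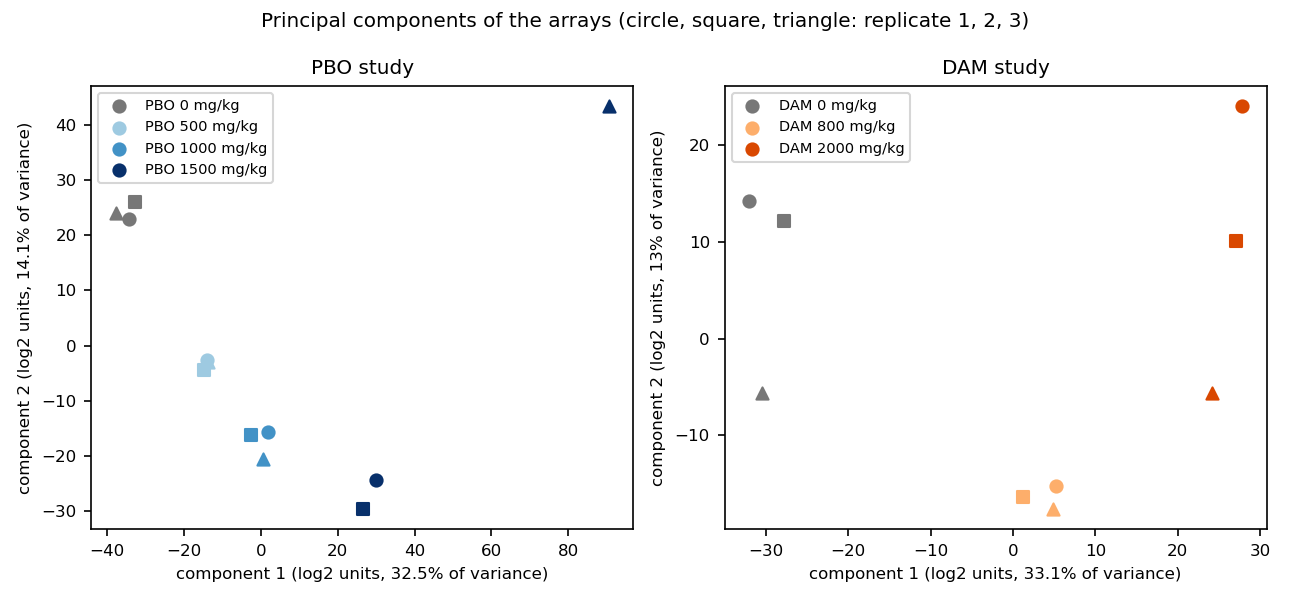
First and second principal components of the arrays of each study, in log2 units, coloured by dose group with circles, squares and triangles for replicates 1, 2 and 3. The first component held 32.5% of the variance in the PBO study and 33.1% in the DAM study, and PBO 1500 replicate 3 lay apart at 90.5.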

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

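The tests of RNA degradation, of the Ugt2b pattern and of the Bcl6 pattern were chosen after the result was seen, and the other tests before.

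The effects of PBO at 1500 mg/kg and DAM at 2000 mg/kg differed for 914 probe sets and 9 gene lists, by a test of the difference itself. Named genes with a difference, PBO minus DAM in log2 units, were Noct (5.12), Pfn2 (3.72), Apoa4 (3.62), Slc66a3 (3.60), Cyp1a1 (3.50), Cyp4a1 (2.07), Cyp2c11 (-1.91), Mme (-4.01), Nrep (-4.16), Dhrs7l1 (-4.30), Stac3 (-4.98) and Car3 (-5.22). The Cyp1a1 call was lost without PBO control replicate 1 or 3, PBO 1500 replicate 1 or 3, DAM control replicate 2 or 3 or DAM 2000 replicate 1 or 2 (adjusted p from 0.0562 to 0.107), and the Dhrs7l1 call without PBO control replicate 2 or DAM 2000 replicate 3 (adjusted p of 0.0522 and 0.0535). Median differences of the lists were 0.68 for PPARalpha targets, 0.46 for NRF2 targets, 0.48 for cell cycle genes, 0.45 for foci markers, -0.19 for ribosomal proteins, -0.37 for acute phase genes, -0.44 for secreted proteins, -0.52 for male-predominant genes and -1.86 for erythroid markers. Of these calls that of NRF2 targets held, with adjusted p = 0.0432 with an estimated correlation. With it the others had adjusted p of 0.143 for PPARalpha targets and foci markers, 0.512 for cell cycle, ribosomal and acute phase genes, 0.507 for secreted proteins, 0.218 for male-predominant genes and 0.0537 for erythroid markers. Of the 9 list calls, 8 were kept with the replicate number as a block and 7 with quantile normalization. Without PBO 1500 replicate 3 the median difference was 0.40 for PPARalpha targets and -0.21 for acute phase genes, and without DAM control replicate 2 it was 0.23 for cell cycle genes. The cell cycle call was lost without DAM control replicate 2 (adjusted p = 0.1), the foci call without PBO control replicate 2 or PBO 1500 replicate 2 or 3 (0.0766, 0.0523 and 0.0847), and the call of 2 further lists without 5 arrays each. These were, for acute phase genes, PBO control replicate 3, PBO 1500 replicate 3, DAM control replicates 1 and 3 and DAM 2000 replicate 1 (0.0621 to 0.166). For ribosomal proteins they were PBO control replicate 2, PBO 1500 replicates 1 and 2, DAM control replicate 1 and DAM 2000 replicate 1 (0.0657 to 0.165). Of 100 splits of the arrays within each study, the real one included, 11 gave as many probe sets and 36 as many lists, with a highest other split of 2534 probe sets and 15 lists, so chance cannot be excluded by this count. The other 10 splits with as many probe sets all kept the PBO groups whole and regrouped the DAM arrays, which leaves the PBO effect in place, and among the 80 that regrouped both studies the highest was 1 probe set.

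For the trend over PBO doses, 1 of 100 splits, the real one with 3122 probe sets, gave as many, and the highest other gave 1068, so a chance arrangement of the animals was excluded at that share. Each comparison of 3 with 3 arrays has 10 splits, too few for a share under 0.05. In them 1 split, the real one, gave as many probe sets in each comparison: 89 at PBO 500 mg/kg (highest other 0), 581 at 1000 (1), 3228 at 1500 (1), 1370 for 1500 against 500 (1), 705 at DAM 800 (0), 2296 at 2000 (0) and 207 for 2000 against 800 mg/kg (1). For lists the real counts and highest others were 14 and 10, 15 and 7, and 12 and 9 for the 3 PBO doses, and 11 and 12, and 12 and 12 for the DAM doses, where 2 splits gave as many. The other splits had a median of 5, 5 and 7 lists for the PBO doses and 6 and 9 for the DAM doses. Their median for probe sets was 0, so the preset correlation called many lists with regrouped arrays too.

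PBO 1500 replicate 3 stood apart from its group on the first principal component (90.5 against 29.9 and 26.7). Degraded RNA is argued against by its Actb log2 ratio of 1.25, the lowest of the 12 PBO arrays. A sample from a lower dose group is argued against by its median position of 1.26 between the 500 mg/kg mean (0) and the other animals of its group (1), above the highest of the 1000 mg/kg animals at 0.382. Its difference from its group correlated across 10670 genes with the change at 1000 mg/kg at 0.0382. That lies under the bound set in advance against a shift further along the same dose response. The other animals of the group had -0.0559 and 0.000689, and the test was not tried on a known shift. The position of 1.26 and the first component both lie beyond the group, so such a shift stays open. What set this animal apart was not tested further and stays open.

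Ugt2b signal was high or low by animal in the PBO study, and low in all 9 F344 animals. A flaw of a single probe set is argued against by the second probe set, whose gap between low and high animals was 4.13 log2 units. Both probe sets agreed in each of the 12 PBO animals, of which 3 were low. That agreement would follow from any real difference in expression, so it does not favour a particular cause. An inherited variant in the outbred stock is an untested candidate explanation, since no genotype was analysed here. An effect of the dose cannot be told apart from it, since 0 of 6 animals were low at 0 and 500 mg/kg and 3 of 6 at 1000 and 1500 mg/kg (Fisher's exact two-sided p = 0.182).

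In the DAM 2000 mg/kg animals Bcl6 was low (-3.83 ± 0.38) while Cish (2.26 ± 0.29) and Onecut1 (1.68 ± 0.33) were high, and none of the 3 passed at 800 mg/kg. There Onecut1 lay in the opposite direction (-1.23 ± 0.33, adjusted p = 0.0631), and passed as lower without DAM control replicate 3 (adjusted p = 0.0316), with only the arrays of both groups (0.0302) and with the replicate number as a block (0.0402). A different time of day at collection cannot be told apart from a dose effect: clock genes of opposite phase differed by 0.525 log2 units, between the bounds set for and against. The phase of Bmal1, Clock and Npas2 had a median change of -0.476, and the other phase, which holds Nr1d1 and Hlf, 0.049. The genes of either phase past the threshold, Bmal1 (-0.476), Npas2 (-0.568) and Hlf (-0.48), all fell. A state of the animal that varies without dose stays open as well, since within dose groups of the 12 PBO animals Bcl6 and Cish had Pearson r = -0.303 (permutation p = 0.297) and Spearman rho = -0.203 (p = 0.533), and r = -0.357 without the 2 farthest animals. Among the 3 relations computed, Bcl6 with Onecut1 had r = -0.894 and rho = -0.839 (permutation p = 0.00873 and 0.0178, adjusted 0.0243 and 0.0306; r = -0.816 without the 2 farthest), and with Socs2 r = -0.884 and rho = -0.832 (p = 0.0162 and 0.0204, adjusted 0.0243 and 0.0306; r = -0.794). Socs2 and the clock genes of this paragraph were chosen apart from the naming rule, as were Cish and Onecut1 against the DAM controls. An effect of the dose itself stays open and untested beyond the comparison.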

How the results depend on the processing

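The fits with array weights, and those at PBO 500 and 1000 mg/kg without PBO 1500 replicate 3, were chosen after the data were seen. No gene result or list call past the threshold changed direction under an alternative. Values that did not pass could change sign, and tests of lists that were not called could turn, such as thyroid hormone targets at PBO 1500 mg/kg (median 0.01, and -0.14 without PBO 1500 replicate 3). The balance of calls turned with median scaling, from 1504 higher and 1724 lower to 1905 and 1203 at PBO 1500 mg/kg, and from 1475 and 1647 to 1876 and 1051 for the trend. It turned for both with quantile normalization too, at PBO 1500 mg/kg with only the arrays of both groups or without PBO control replicate 1 or 3, and for 1500 against 500 without any 1 PBO 1500 array. At DAM 2000 mg/kg it turned without the intensity trend and with only the arrays of both groups. Of 985 gene results, 704 kept their side of the threshold under every alternative, 136 lost it and 145 gained it under at least 1; of 73 called lists, 61 lost their call at least once, all of them with the estimated correlation. With that correlation 4, 5 and 2 lists were called at PBO 500, 1000 and 1500 mg/kg, 0 and 0 at DAM 800 and 2000 mg/kg, and 1 for the difference. Without the intensity trend, 45 and 300 probe sets passed at PBO 500 and 1000 mg/kg, 801 for 1500 against 500, 235 and 1501 at DAM 800 and 2000 mg/kg and 60 for 2000 against 800. With only the arrays of both groups, 269, 1370 and 1550 passed at PBO 500, 1000 and 1500 mg/kg and 245 for 1500 against 500. Array weights gave 348 and 1443 at PBO 500 and 1000 mg/kg. Leaving out 1 array gave 52 to 371 at PBO 500, 255 to 1448 at PBO 1000, 2032 to 3321 at PBO 1500, 613 to 1976 for 1500 against 500, 382 to 575 at DAM 800, 1492 to 1882 at DAM 2000, 121 to 198 for 2000 against 800 and 502 to 1425 for the difference. Arrays of groups outside a comparison were not left out, apart from PBO 1500 replicate 3 at PBO 500 and 1000 mg/kg. Fewer arrays per group lower the residual degrees of freedom. The highest counts at PBO 500 and 1000 mg/kg, 371 and 1448, came without PBO 1500 replicate 3, which is in neither comparison. There it acts only through the residual spread shared by all PBO arrays and the filter on dim probe sets. Its root mean square deviation from its group mean was 0.495, and no other PBO array exceeded 0.368. Its inclusion thus held down both counts. At PBO 1500 mg/kg the count went the other way, from 3228 with the shared spread to 1550 with only the arrays of both groups. Fewer residual degrees of freedom also act there. Other causes of these ranges were not tested. The counts for the trend, and the list counts when 1 array was left out, stayed within 1.5 times.

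Same-numbered arrays had deviations correlated from -0.072 to 0.034 in the PBO study, where 2 of 12 arrays correlated best with their own number. Replicate numbers thus showed no pairing there. In the DAM study the range was -0.062 to 0.1, with a median of 0.012 beside -0.002 for other numbers. There 6 of 9 arrays correlated best with their own number, so a weak pairing cannot be excluded. No chance level was computed. With the replicate block the counts were 87, 475, 2994, 1179, 2821, 630, 2043, 172 and 726, for PBO 500, 1000 and 1500 mg/kg, 1500 against 500, the trend, DAM 800 and 2000 mg/kg, 2000 against 800 and the difference. Signal near background limits dim genes, whose changes the added 16 shrinks.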

Other observations

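The descriptions here were chosen after the results were seen.

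The list of ER stress and ATF4 targets was not called at PBO 1500 mg/kg (camera adjusted p = 0.667, 4 rises and 3 falls among 22, 5 and 4 adjusted over the list alone). The median of that list was -0.14, its mean 0.32 and its test pointed up. Its 4 members with the smallest adjusted p rose. Phgdh and Psat1, enzymes of serine synthesis, rose by 3.72 ± 0.49 and 2.42 ± 0.31, the pseudokinase Trib3 by 2.37 ± 0.45 and asparagine synthetase Asns by 2.03 ± 0.42. Psat1 also rose by 2.29 ± 0.37 at DAM 2000 mg/kg. Of haem genes, Blvrb, Hmox1 and Alas1, the first enzyme of haem synthesis, rose by 1.72 ± 0.17, 1.97 ± 0.33 and 1.88 ± 0.35 at PBO 1500 mg/kg. That list had 3 rises among 10 (3 adjusted over the list alone), with a camera adjusted p = 0.0837. Hmox1 also belongs to the NRF2 list and Alas1 to the CAR/PXR list, so these rises are not separate from the counts there. Mdm2, a p53 target, rose by 1.02 ± 0.15 at PBO 1500 and by 1.31 ± 0.09 at DAM 2000 mg/kg, while the p53 list was not called in either (camera adjusted p of 0.386 and 0.919). The median of that list at PBO 1500 mg/kg was -0.04 (0.03 without PBO 1500 replicate 3) and its mean 0.14, and at DAM 2000 mg/kg 0.07 and -0.01; both tests pointed up.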
